A study of Homo sapiens with 42 samples.

How the data were processed

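Gene expression was measured by RNA sequencing in 42 cultures of vorinostat-resistant HCT116 cells: 14 groups of siRNA, compound and time, with 3 libraries each. Per the labels' protocols, cells were reverse transfected with 40 nM of a pooled siRNA or with lipid alone, treated after 48 h with 2.5 uM vorinostat or DMSO, and harvested 4, 8 or 12 h later. Poly(A) RNA was sequenced with an unstranded kit. There was no non-targeting siRNA: mock cells received lipid only, so each siRNA is compared with the absence of any siRNA. Samples were assigned to groups from the titles. The titles of siPSMD13 cells with DMSO at 12 h spell the target siPSDM13, and these 3 libraries were placed with siPSMD13. The submitters' processing notes name CASAVA 1.8.2, FastQC, HTSeq, TopHat2 2.0.8b, limma and the genome build GRCh37, with no roles.

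The authors deposited 1 table of log2 CPM (read counts scaled to library size) for 14773 Ensembl genes in 42 libraries, as limma's voom writes them, with 0.5 reads added before the log. This was tested on the file: undoing the formula gave whole read counts in every cell, the largest distance from a whole number being 1.8e-08. The recovered totals were 13379126 to 24394899 reads per library, with scaling factors of 0.941 to 1.09. How the authors chose these genes is not stated; the lowest sum of reads over the 42 libraries was 111. The median of tested genes was 4.28 log2 CPM, and GLI1 had 15 reads or fewer in mock cells with DMSO at 4 and 8 h, where counting error is largest. Gene symbols came from the reference annotation by Ensembl identifier, which gave a symbol for 14364 of 14773 genes. The authors' build is GRCh37 and the reference is GRCh38, so no coordinates are given. Genes that share sequence with paralogs (AKR1C1 and AKR1C2, HSPA1A and HSPA1B) or overlap a gene on the other strand can exchange reads and are uncertain one by one.

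Genes with a log2 value above 0 in at least 3 libraries were tested (14603). A linear model with 1 mean per group was fitted to the deposited values with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. It gave 23 comparisons: vorinostat against DMSO in each arm and time, each siRNA against mock with DMSO and with vorinostat, siGLI1 against siPSMD13 at 8 h, and differences of the vorinostat response between arms and between times in mock cells. P-values were adjusted within each comparison by Benjamini-Hochberg, and a gene is called at an adjusted p under 0.05. Errors are SE of the log2 fold change, from 1 spread per gene that all 14 groups share. The design text describes 3 independent experiments of 14 samples, so the replicate number marks a shared experiment. Its effect was checked from residuals: libraries of the same number had a median r of 0.049 (273 pairs) and of different numbers -0.024 (546 pairs). An r above 0.1 was found in 58 pairs of the same number and in 2 of different numbers, so an effect of the experiment was present. The number was used as a block in an alternative.

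A set of 25 gene lists was written before the data were examined: 19S and 20S proteasome, ubiquitin and p97, Hedgehog, heat shock, integrated stress response, endoplasmic reticulum chaperones, NRF2, p53, G2/M, G1/S, pro-apoptotic and pro-survival BCL2 family, HDACs and sirtuins, genes reported to rise with HDAC inhibitors, neuronal, cholesterol, interferon, WNT, immediate early, colon epithelium, mesenchymal, leukocyte, ribosomal protein and mitochondrially encoded genes. They held 334 tested members. The leukocyte list had 0 tested members, and the other 24 were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of list members use the adjustment over all genes, and a second adjustment over the list alone is given where it differs.

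The rule for named genes was fixed at the same time. In each family of comparisons it took, at 8 h, the 5 highest and 5 lowest log2 fold changes among genes with an adjusted p under 0.05 and a mean at or above the median of tested genes. It also asked for no overlap between the libraries of the compared groups (which chance alone gives in 10% of genes with 3 against 3) and for the same direction with an adjusted p under 0.05 at the other times. For differences of response only the same direction was asked. Genes without a symbol and clone names were skipped. From each list it took up to 3 called members with the largest change and up to 2 not called with the highest mean. Some genes taken by the rule are not reported here. GLI1 and PSMD13 were always named.

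The level of each target was compared through recovered reads, with exact intervals for the ratio of counts and a floor of 3 counts over the group where a group had 0 reads. Overlap of the siRNA effects was set against 100 simulations of unchanged groups that share the controls. Words of 7 bases were searched in 3' UTRs of the reference transcripts, present for 11977 of the tested genes, by a regression of log2 fold change on the presence of each word with UTR length, base composition and mean expression in the model, and 100 shuffles of the genes gave the lowest z without any link. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for words and figures.

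The pipeline was tested on simulated data. With 100 genes changed 1.5-fold or 2-fold between groups of 3, limma recovered 76% and 96%, with 7 unchanged genes called, and for a difference of responses 55% and 85%, with 10. With no change, 0 genes were called. A 19S list shifted by 0.5 was recovered with both correlations, with 0 of 23 unchanged lists called. The simulated genes were drawn independently, so this run cannot show whether the preset correlation is high enough for the real lists. A planted word effect of 0.1 was recovered in 8 of 10 runs and one of 0.2 in 10 of 10.

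The alternatives planned were the replicate number as a block, only the libraries of the groups compared, no filter, a stricter filter (log2 above 3 in at least 3 libraries), quantile normalization, a shift of each library to the same median, no intensity trend, the omission of each replicate number in turn, and for lists an estimated correlation. A change of pseudocount applies to linear values only and was not run. Voom weights on the recovered reads were added after seeing the data.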

Results

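RNA sequencing was used to measure gene expression in a vorinostat-resistant derivative of HCT116, a human colorectal carcinoma line. Vorinostat inhibits histone deacetylases (HDACs). Cells were reverse transfected with an siRNA pool against GLI1, the transcription factor at the end of the Hedgehog pathway, with a pool against PSMD13, a subunit of the 19S regulatory particle of the proteasome, or with lipid alone (mock). After 48 h they received 2.5 uM vorinostat or its solvent DMSO. Mock cells were harvested at 4, 8 and 12 h, siGLI1 cells at 4 and 8 h, and siPSMD13 cells at 8 and 12 h. This gave 14 groups of 3 libraries, 42 in all, with 1 library of each group from each of 3 independent experiments. The libraries held 13379126 to 24394899 reads, and 14603 genes were tested. The comparisons ask what each knockdown does to the transcriptome of these cells, what vorinostat does, and where the knockdown changes the response to vorinostat. Log2 fold changes are given with their SE and with limma's adjusted p. The SE uses 1 spread per gene shared by all 14 groups of 3 libraries, not the spread of the 2 groups compared.

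The targeted genes were measured first. GLI1 (ENSG00000111087) was near the detection limit in mock cells with DMSO, with 6 to 15 reads per library at 4 h and 6 to 12 at 8 h. With siGLI1 and DMSO, 3 reads remained over the 3 libraries at 4 h against 28 in mock cells, an 8.58-fold lower level (95% interval 2.65 to 44.1). At 8 h the counts were 0 against 26, with an exact 95% lower bound of 5.69-fold for the difference. A floor of 3 counts over the group in place of 0 gives 7.51-fold, which is a minimum and not an estimate. Vorinostat raised GLI1 in mock cells by 2.94 ± 0.46 at 4 h (adjusted p = 4.1e-07), 3.06 ± 0.46 at 8 h (1.4e-07) and 1.64 ± 0.46 at 12 h (0.0017) on the log2 scale. Mean log2 CPM in mock cells with vorinostat was 2.13, 2.17 and 2.09 at these times, against -0.81, -0.89 and 0.44 with DMSO. The smaller rise at 12 h thus goes with a higher level with DMSO. With vorinostat, GLI1 was 24.7-fold lower in siGLI1 than in mock cells at 4 h (8 against 209 reads, 95% interval 12.3 to 58) and 18.4-fold lower at 8 h (13 against 262 reads, 95% interval 10.6 to 35.1). These intervals cover counting error only.

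PSMD13 (ENSG00000185627) had 4544 to 8027 reads in each mock library at 8 and 12 h and 66 to 119 in each siPSMD13 library. It was 55.9-fold lower at 8 h and 52.9-fold lower at 12 h with DMSO, and 64.1-fold and 59.5-fold lower with vorinostat. Its mean at 8 h with DMSO was 8.33 ± 0.08 log2 CPM in mock cells and 2.53 ± 0.19 in siPSMD13 cells (SD, n = 3). Pooled over the 4 pairs of groups, each target was lower in its 12 siRNA libraries than in the 12 mock libraries (exact stratified permutation test, two-sided p = 1.25e-05 for each gene, the smallest the 160000 arrangements can give). The arrangements treat all libraries as independent, though the 4 pairs of groups repeat the same 3 experiments. This p therefore does not measure the spread between experiments and is too small for 3 of them. PSMD13 was slightly higher with siGLI1, by 0.27 to 0.33 (adjusted p = 0.0037 to 0.018 over the 4 comparisons). GLI1 fell with siPSMD13 and DMSO, by -1.34 ± 0.46 at 8 h (adjusted p = 0.012) and -1.86 ± 0.46 at 12 h (0.00065). With siPSMD13 and vorinostat its values of -0.96 (0.084) and -0.91 (0.095) did not pass the test, whose SE is shared by all groups. Yet with vorinostat at 8 h GLI1 had 2.17 ± 0.13 log2 CPM in mock and 1.21 ± 0.09 in siPSMD13 cells (SD, n = 3). Each library had 63 to 112 and 38 to 53 reads. At 12 h the means were 2.09 ± 0.11 and 1.18 ± 0.32. With DMSO at 8 h the reads were only 6 to 12 and 2 to 4. A fall confined to DMSO is therefore not shown.

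**Figure D1:**
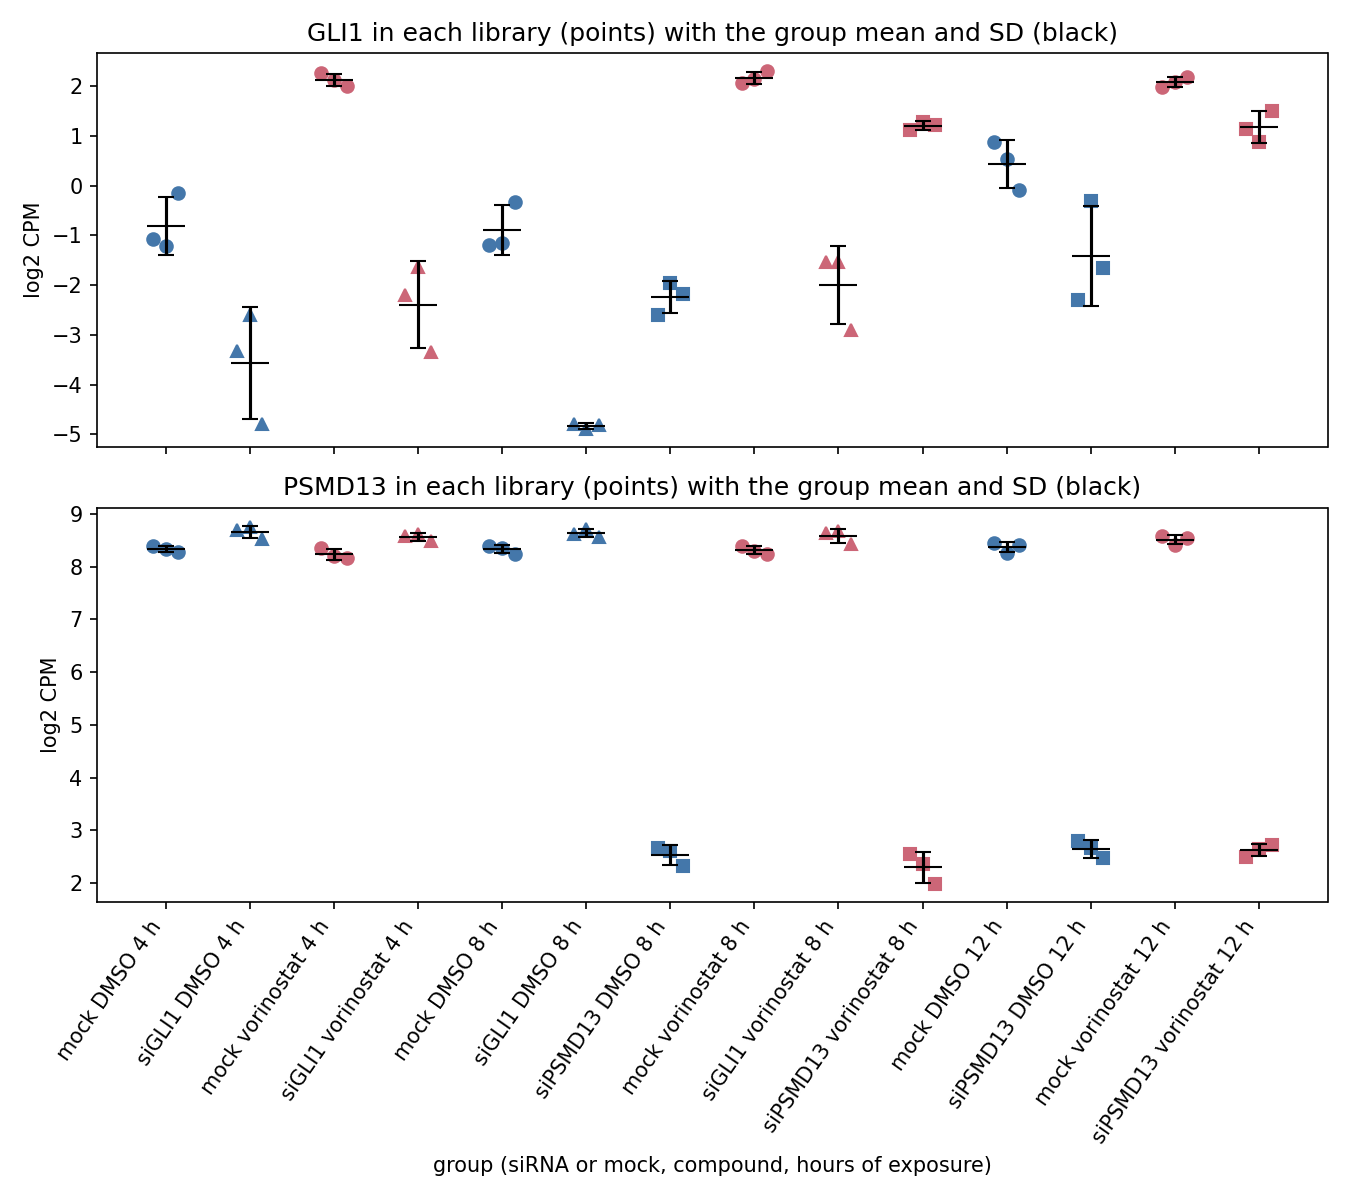
Log2 CPM of GLI1 (top) and PSMD13 (bottom) in each of the 42 libraries by group, blue with DMSO and red with vorinostat, circles for mock, triangles for siGLI1 and squares for siPSMD13 cells, with the group mean and SD in black. PSMD13 lies at 1.98 to 2.80 in the siPSMD13 libraries and at 8.16 or above in all others, and the lowest GLI1 points are libraries with 0 reads, which stand at the value of the 0.5 reads added before the log.

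The libraries separated by treatment. The first principal component held 45.0% of the variance and set the DMSO libraries (-56.3 to -40.1) apart from the vorinostat libraries (17.0 to 65.4). The second held 20% and set siGLI1 cells (44.5 to 54.0) apart from mock (-18.8 to -3.7) and siPSMD13 cells (-36.7 to -22.8), so that the siRNA arms moved in opposite directions from mock on this axis. On the third, with 11.9%, both arms lay on the same side of mock (mock 20.6 to 31.8, siGLI1 -15.0 to -3.6, siPSMD13 -38.0 to -21.5). No pair of libraries of 1 group agreed within sampling noise, the lowest chi-square per gene being 2.975.

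**Figure D2:**
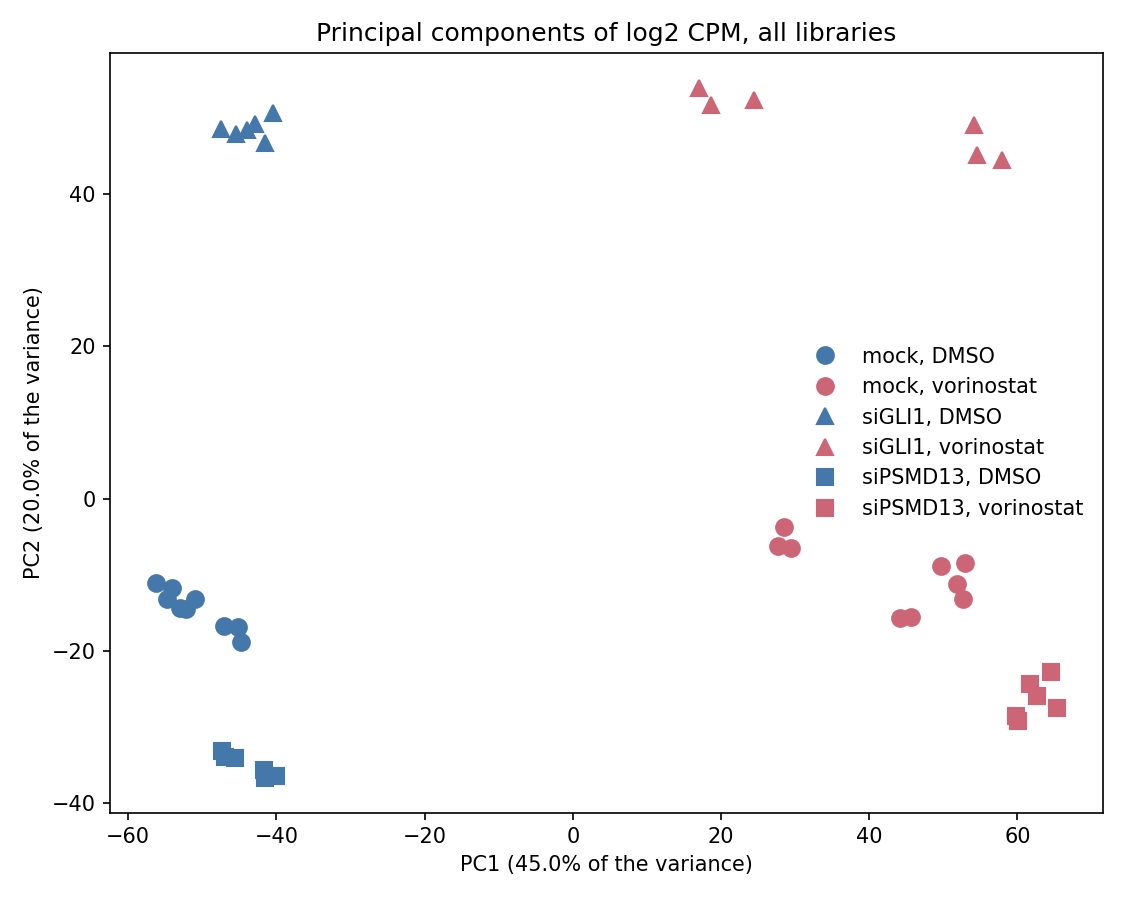
First and second principal components of log2 CPM over the 42 libraries (points), with 45.0% and 20% of the variance, coloured by compound and shaped by siRNA. Vorinostat libraries lie at 17.0 or above on the first component and siGLI1 libraries at 44.5 or above on the second.

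Vorinostat changed the expression of most genes in mock cells. At 8 h the largest increases among well expressed genes (here and below, those with a gene symbol and a mean at or above the median of tested genes) were in CCN2 (ENSG00000118523), a matricellular growth factor, at 13.4-fold (3.74 ± 0.17, adjusted p = 1.9e-22), and the aquaglyceroporin AQP3 (8.15-fold, 3.03 ± 0.11, 2.3e-25). DHRS2, a short-chain dehydrogenase, rose by 2.90 ± 0.10, the CDK4/6 inhibitor gene CDKN2B by 2.74 ± 0.13 and the formin gene DAAM1 by 2.66 ± 0.12. The deepest fall among these genes was in HMGA2 (ENSG00000149948), an architectural chromatin protein (9.23-fold lower, -3.21 ± 0.14, 6.5e-23). It was followed by TM4SF18 (-2.77 ± 0.15), PHLDB2 (-2.67 ± 0.11), the adhesion receptor ADGRF1 (-2.60 ± 0.15) and the lymphotoxin beta receptor LTBR (-2.53 ± 0.11). The rule that picked these 10 genes required that the libraries of the 2 groups did not overlap. It also required a call in the same direction at 4 and 12 h.

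Genes reported to rise with HDAC inhibitors rose here. Of 12 measured, 11 were higher at 8 h (median 1.16, camera adjusted p = 5.6e-05, adjusted p = 0.079 with an estimated correlation), among them glutaredoxin GLRX (2.20 ± 0.09) and the extracellular chaperone clusterin, CLU (1.71 ± 0.11). H2BC21 had 0.38 ± 0.25 and was not called. Neuronal genes rose from low levels in 7 of 10 (median 1.39, 0.01, adjusted p = 0.28 with an estimated correlation), with the synaptic vesicle genes SYT11 at 2.90 ± 0.35 and SYP at 2.61 ± 0.32. In the mesenchymal list 6 of 7 rose (median 0.89, 0.033, adjusted p = 0.44 with an estimated correlation), with fibronectin FN1 at 2.17 ± 0.24 and ZEB1 at 1.04 ± 0.19, and SNAI2 went from 2 to 92 reads. In cholesterol synthesis and uptake, 13 of 17 genes rose and 3 fell (0.026, adjusted p = 0.44 with an estimated correlation), including STARD4 (1.00 ± 0.12), INSIG1 (0.92 ± 0.11) and IDI1 (0.81 ± 0.08). Of 16 endoplasmic reticulum chaperone genes 12 rose, with SEL1L (0.82 ± 0.07) and HSPA5 (0.82 ± 0.07) highest, and 2 fell, with XBP1, a transcription factor of this programme, at -1.20 ± 0.06 (list 0.034, adjusted p = 0.44 with an estimated correlation).

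Cell cycle genes fell. Of 21 G1/S and replication genes 15 were lower and 1 higher (median -0.39, camera adjusted p = 0.0023, adjusted p = 0.44 with an estimated correlation), with MCM3 (-1.16 ± 0.07), MCM5 (-1.15 ± 0.08) and thymidylate synthase TYMS (-1.10 ± 0.07) lowest. Of 20 G2/M and mitosis genes 11 fell and 2 rose (median -0.40, 0.0023, adjusted p = 0.44 with an estimated correlation), with the mitotic kinase gene PLK1 at -1.18 ± 0.09 and FOXM1 at -1.01 ± 0.11. TOP2A (-0.04 ± 0.09) was not called, nor was CDC20 (-0.00 ± 0.08), which quantile normalization put at 0.20 (adjusted p = 0.016; 0.58 to 0.99 in the other settings).

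Proteasome genes were moderately lower with vorinostat in mock cells at 8 h. In the 19S regulatory particle 12 of 17 genes fell and 1 rose (median -0.40, camera adjusted p = 0.0038, adjusted p = 0.44 with an estimated correlation), with PSMD11 at -0.82 ± 0.07, PSMD7 at -0.77 ± 0.06 and PSMC5 at -0.62 ± 0.06. In the 20S core 11 of 13 fell (median -0.33, 0.022, adjusted p = 0.54 with an estimated correlation), with PSMB5 at -1.02 ± 0.07. The integrated stress response list had 9 of 16 genes lower and 3 higher (median -0.47, 0.035, adjusted p = 0.44 with an estimated correlation). TRIB3 (-2.06 ± 0.06), the cystine transporter SLC7A11 (-1.88 ± 0.15) and ATF4 (-1.27 ± 0.12) fell most. Ribosomal protein genes fell in 15 of 22 (18 adjusted over the list alone; median -0.23, 0.032, adjusted p = 0.63 with an estimated correlation), RPL4 the most at -0.35 ± 0.06.

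In 13 other lists members moved both ways or the list did not pass. Of 22 p53 target genes 13 rose and 7 fell (camera adjusted p = 0.17), with the CDK inhibitor gene CDKN1A at 1.19 ± 0.09 and PLK2 at 1.15 ± 0.12. Heat shock genes rose in 6 and fell in 9 of 18 (0.42), with DNAJB1 at 1.75 ± 0.10 and SERPINH1 at -1.37 ± 0.08. In the Hedgehog list 5 of 9 rose and 1 fell (0.22), with the co-receptor gene CDON at 1.52 ± 0.13 and SMO at -1.30 ± 0.10. Of 7 colon epithelium genes 5 rose and 2 fell (0.22), with E-cadherin, CDH1, at 1.43 ± 0.06 and CDX2 at -1.15 ± 0.10. Of 11 WNT targets 5 rose and 4 fell (0.86), with CCND1 at -1.48 ± 0.10. The NRF2 list had 3 of 12 higher and 3 lower (2 and 2 adjusted over the list alone; 0.87, its test leaning up and its median of -0.05 down), and the ubiquitin and p97 list 4 of 16 higher and 5 lower (0.53). Mitochondrially encoded genes had 1 of 9 higher (0 adjusted over the list alone; 0.72). The HDAC and sirtuin, interferon, BCL2 family and immediate early lists are described among the other observations.

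In all, 9965 of 14603 genes were called with vorinostat in mock cells at 8 h (5058 higher, 4907 lower), of which 1749 were at least 2-fold higher and 1063 at least 2-fold lower. The counts were 8740 at 4 h (4323 higher, 4417 lower) and 9600 at 12 h (4776 higher, 4824 lower). Of 7543 genes called at both 4 and 8 h, 7451 changed in the same direction, and of 8127 called at both 8 and 12 h, 8031. Unless another count is given, counts in a list were the same adjusted over the list alone. With an estimated correlation none of the 11 list calls at 8 h held. The calls of 6 of these 11 lists also ended with other settings, given with the range over all other settings: integrated stress response (adjusted p = 0.084 with the stricter filter, 0.13 with quantile normalization, 0.056 without replicate 2 and without replicate 3; 0.017 to 0.13), 19S (0.1 with quantile normalization; 0.0019 to 0.1), 20S (0.05 and 0.19 with the stricter filter and quantile normalization; 0.0048 to 0.19), endoplasmic reticulum chaperones (0.05 with the stricter filter; 0.012 to 0.05), mesenchymal (0.051 and 0.076 with the stricter filter and quantile normalization; 0.021 to 0.076) and ribosomal proteins (0.067 and 0.49 with these settings, 0.07 without replicate 2; 0.0019 to 0.49). The lists called also depended on the time. The G1/S and HDAC inhibitor lists were called at 4 h (camera adjusted p = 0.01 and 0.005) and 12 h (0.00093 and 6.8e-06) too. The G2/M (0.00015), 19S (0.015) and ribosomal protein (0.033) lists were called at 4 h and not at 12 h (0.12, 0.07 and 0.24), and the integrated stress response (0.0071), neuronal (0.012) and mesenchymal (0.021) lists at 12 h and not at 4 h (0.75, 0.066 and 0.12). The 20S (0.058 at 4 h and 0.12 at 12 h), endoplasmic reticulum chaperone (0.59 and 0.24) and cholesterol (0.093 and 0.52) lists were called at 8 h alone. The heat shock list was called at 12 h alone, with 11 of 18 genes lower and 3 higher (median -0.35, 0.012, adjusted p = 0.7 with an estimated correlation). Of the calls at 4 and 12 h only that of the HDAC inhibitor list at 12 h held with an estimated correlation (0.039).

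Knockdown with siGLI1 changed many genes in the absence of vorinostat. Among well expressed genes at 8 h with DMSO, CDKN2B (ENSG00000147883) rose 13.8-fold (3.78 ± 0.13, adjusted p = 1.8e-25) and the carboxypeptidase CPA4 7.19-fold (2.85 ± 0.14, 3.5e-20). They were followed by CITED2, a CBP/p300-binding transcriptional regulator (2.72 ± 0.10), TUFT1 (2.19 ± 0.11) and CLU (2.18 ± 0.11). Among the same well expressed genes, the ETS factor ETV4 (ENSG00000175832) fell 9.51-fold (-3.25 ± 0.10, 2.5e-27) and the focal adhesion gene TNS4 9.29-fold (-3.22 ± 0.13, 6.7e-24). Next among them were BTBD2 (-3.01 ± 0.09), transglutaminase TGM2 (-2.87 ± 0.19) and the ecto-nucleotidase NT5E (-2.77 ± 0.14). The rule that picked these 10 genes required a call in the same direction at 4 h. The genes that fell were enriched for short words in their 3' UTRs that also stand in the GLI1 transcript. The word GTGTGTA, present in 1985 of 11977 genes, had a z of -15.4 at 8 h and -17.3 at 4 h, and the lowest z over 100 shuffles of the genes at 8 h was -4.7. GCAATGC (-9.8 at 8 h) and TCCACTC (-7.4) were the other 2 leading words. Leading words were the lowest at 4 h that shared no run of 4 bases with a word taken before. BTBD2 and TGM2 hold GCAATGC and TCCACTC, NT5E and CLU hold GTGTGTA, and ETV4, TNS4 and the other 4 named genes hold none of them.

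**Figure D3:**
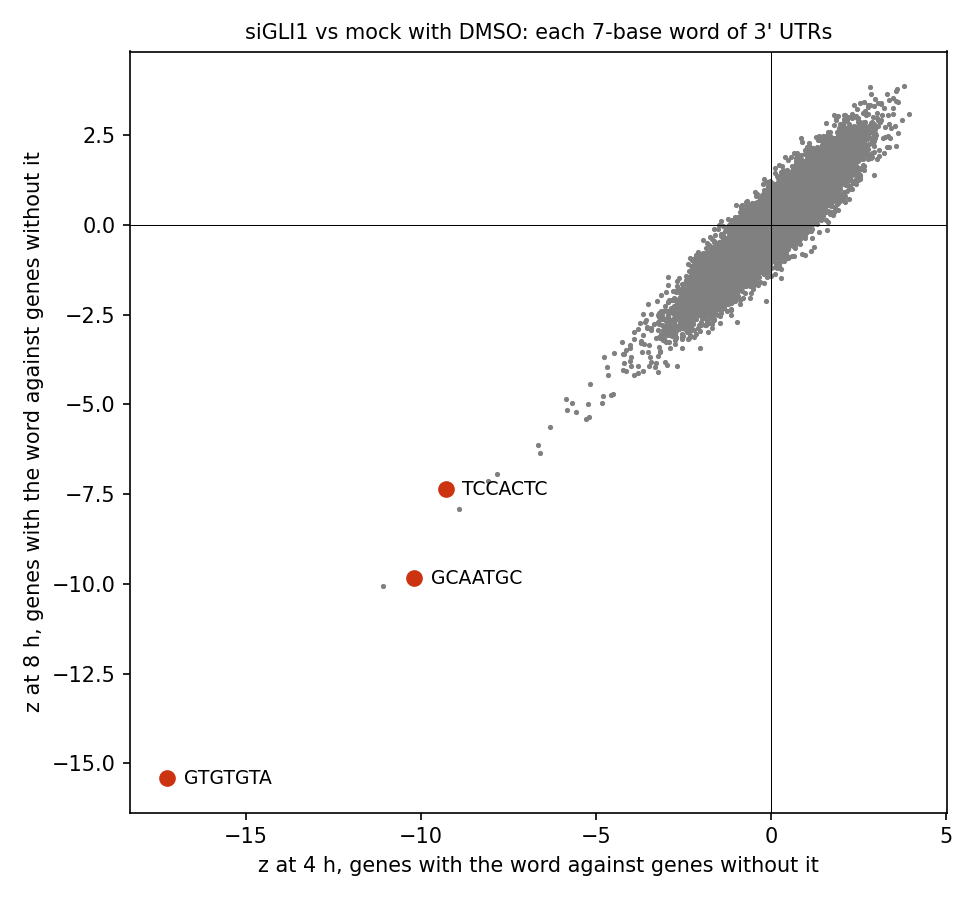
Z of each of 15920 7-base words of 3' UTRs for siGLI1 against mock with DMSO, at 4 h (horizontal) and at 8 h (vertical); a negative z means that genes with the word were lower than genes without it. The 3 leading words are marked in red, with GTGTGTA lowest at both times (-17.3 and -15.4), and unmarked points near them are words that overlap these.

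The G1/S and replication genes fell with siGLI1. Of 21, 19 were lower at 8 h (20 adjusted over the list alone; median -0.54, camera adjusted p = 4e-07, adjusted p = 0.25 with an estimated correlation), with MCM2 (-1.51 ± 0.09), cyclin E1, CCNE1 (-1.50 ± 0.08), and E2F1 (-1.47 ± 0.10) lowest, and POLE at -0.03 ± 0.08 not called. Of 20 G2/M and mitosis genes 18 fell and 1 rose (median -0.39, 0.00025, adjusted p = 0.40 with an estimated correlation), with the kinase gene AURKA at -1.35 ± 0.06, CENPF at -0.91 ± 0.16 and BUB1B at -0.83 ± 0.08, and BIRC5 at 0.01 ± 0.06. p53 target genes rose in 17 of 22 and fell in 2 (median 0.39, 7.5e-05, adjusted p = 0.14 with an estimated correlation), with BTG2 at 2.58 ± 0.12, BBC3 at 1.55 ± 0.12 and PLK2 at 1.22 ± 0.12. NRF2 targets rose in 11 of 12 (median 0.51, 2e-04, adjusted p = 0.14 with an estimated correlation), with heme oxygenase HMOX1 at 1.02 ± 0.10 and ferritin FTH1 at 0.93 ± 0.09. Genes reported to rise with HDAC inhibitors rose in 10 of 12 without the drug (median 0.57, 0.00049, adjusted p = 0.14 with an estimated correlation), with CLU, H1-2 (1.67 ± 0.13) and H2BC5 (1.36 ± 0.19) highest and MT2A at 0.01 ± 0.14. Pro-apoptotic BCL2 family genes rose in 8 of 13 and fell in 2 (median 0.64, 0.0097, adjusted p = 0.16 with an estimated correlation), with BBC3, PMAIP1 (1.18 ± 0.08) and BIK (0.89 ± 0.11) highest.

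Of 11 WNT target genes 8 fell and 1 rose with siGLI1 (median -0.51, camera adjusted p = 0.023, adjusted p = 0.23 with an estimated correlation). NOTUM fell by -3.10 ± 0.21 and TCF7 by -1.22 ± 0.09, while AXIN2, a feedback inhibitor of the pathway, rose by 1.31 ± 0.12. Neuronal genes fell in 6 of 10 and rose in 1 (0.045, adjusted p = 0.25 with an estimated correlation), with VGF at -1.57 ± 0.13 and STMN3 at -0.99 ± 0.07. All 9 mitochondrially encoded genes rose (median 0.87, 0.0097, adjusted p = 0.61 with an estimated correlation), MT-CYB by 1.04 ± 0.19, and together they took 3.62% ± 0.863 of reads against 2.13% ± 0.567 in mock cells (SD, n = 3). The Hedgehog list, the pathway of the targeted gene, had 5 of 9 genes lower and 2 higher and did not pass as a list (median -0.54, 0.52, and 0.59 at 4 h). BOC fell by -1.91 ± 0.33, FOXL1 by -2.40 ± 0.48 (28 to 4 reads) and GAS1 by -1.49 ± 0.32 (53 to 15 reads), and SMO had -0.06 ± 0.10. In the ubiquitin and p97 list 8 rose and 5 fell of 16 (0.93), with DDI2 at -1.61 ± 0.09. The 20S core had 6 of 13 genes higher (0.16), and the 19S particle 5 of 17 higher and 4 lower (3 and 3 adjusted over the list alone; 0.91). Ribosomal protein genes were higher in 8 of 22 and lower in 1 (0.054; 0.034 with the replicate number as a block, 0.0076 without replicate 3 and 0.005 to 0.51 over all other settings).

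In all, siGLI1 changed 8458 genes at 8 h with DMSO (4058 higher, 4400 lower; 575 and 1019 at least 2-fold) and 8496 at 4 h (4273 higher, 4223 lower), of which 6981 were called at both times and 6972 of these in the same direction. With vorinostat present the counts were 8217 at 4 h (4373 higher, 3844 lower) and 7770 at 8 h (3769 higher, 4001 lower). At 8 h with vorinostat 48.5% of the calls were higher, and 59.5% after each library was shifted to the same median. At 8 h with DMSO, 7SK RNA, which lacks a poly(A) tail, was 4.32 ± 0.71 higher in siGLI1 cells (adjusted p = 1.4e-06). At 4 h it was not called (-0.99 ± 0.71, 0.23), and carry-over of such RNA between libraries is weighed among the flagged results. None of the 9 list calls held with an estimated correlation. The neuronal call also ended among only the compared groups (0.055), with quantile normalization (0.06), without replicate 1 (0.064) and with voom weights (0.073; 0.031 to 0.073 over all other settings), and the WNT call with the stricter filter (0.098; 0.007 to 0.098). At 4 h the same 9 lists were called (camera adjusted p = 1.9e-05 to 0.034), and the ribosomal protein list as well (0.026, 14 of 22 higher and 1 lower), none of them with an estimated correlation (0.16 to 0.75).

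Knockdown with siPSMD13 raised the other genes of the proteasome. At 8 h with DMSO all 17 tested 19S genes were higher (median 0.96, camera adjusted p = 8.6e-19, adjusted p = 0.02 with an estimated correlation), with PSMC4 at 1.23 ± 0.07, PSMD6 at 1.14 ± 0.06 and PSMD2 at 1.14 ± 0.08. The list left out PSMD13 itself. All 13 tested 20S core genes rose too (median 0.90, 5.4e-13, adjusted p = 0.044 with an estimated correlation), led by PSMB6 (1.37 ± 0.07), PSMB2 (1.32 ± 0.06) and PSMB7 (1.10 ± 0.06). In the ubiquitin and p97 list 13 of 16 rose (median 0.78, 1.2e-09, adjusted p = 7e-06 with an estimated correlation), with the autophagy receptor SQSTM1 at 1.95 ± 0.07 and the p97 cofactor UFD1 at 1.14 ± 0.06. UCHL5 (0.03 ± 0.07) and DDI2 (-0.14 ± 0.09) were not called.

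Genes of the oxidative stress response rose with siPSMD13. Of 12 NRF2 targets 11 were higher (11 higher and 1 lower adjusted over the list alone; median 0.92, camera adjusted p = 5.6e-11, adjusted p = 0.0015 with an estimated correlation). OSGIN1 (ENSG00000140961) rose 8.12-fold (3.02 ± 0.12, 8.7e-24), ferritin FTL by 1.69 ± 0.07, and AKR1B10 by 6.14 ± 0.61, from 4 to 377 reads over the group. p53 targets rose in 17 of 22 and fell in 1 (median 0.64, 5.2e-08, adjusted p = 0.02 with an estimated correlation), with CDKN1A at 1.66 ± 0.09, the stress cytokine GDF15 at 1.49 ± 0.15 and the death receptor FAS at 1.40 ± 0.12. Other well expressed genes with large increases were biliverdin reductase BLVRB (2.47 ± 0.09), the hydrolase ABHD4 (2.47 ± 0.10), laminin subunit LAMB3 (2.41 ± 0.08) and lipase LIPH (2.39 ± 0.12). After PSMD13, the deepest falls among well expressed genes were in the myosin MYO1D (-2.53 ± 0.13), TULP3, a ciliary trafficking gene (-2.51 ± 0.09), the DNA glycosylase NEIL2 (-2.32 ± 0.08) and SKI, a corepressor of TGF-beta signalling (-2.13 ± 0.08). The rule that picked the well expressed genes required a call in the same direction at 12 h.

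Cell cycle genes fell with siPSMD13 as well. Of 21 G1/S genes 15 fell and 1 rose (median -0.47, camera adjusted p = 2.1e-05, adjusted p = 0.39 with an estimated correlation), with E2F1 at -1.44 ± 0.10, CCNE2 at -0.85 ± 0.11 and PCNA, not called, at -0.01 ± 0.05. Of 20 G2/M genes 17 fell (19 adjusted over the list alone; median -0.38, 0.00011, adjusted p = 0.39 with an estimated correlation), CCNB2 by -0.62 ± 0.06, and AURKA had -0.01 ± 0.06. Of 11 WNT targets 9 fell and 1 rose (median -0.87, 0.0031, adjusted p = 0.068 with an estimated correlation), with NOTUM at -2.02 ± 0.21 and AXIN2 at -1.57 ± 0.12. Interferon-responsive genes rose in 6 of 13 (median 0.48, 0.043, adjusted p = 0.39 with an estimated correlation), with IRF7 at 1.25 ± 0.21 and IFIT2 at 1.09 ± 0.37 (without replicate 2 its adjusted p was 0.075, and 9.8e-05 to 0.075 over all other settings). The Hedgehog list had 7 of 9 genes lower and 1 higher (8 and 1 adjusted over the list alone; 0.052), with GAS1 at -2.09 ± 0.32 (53 to 11 reads) and GLI2 at -1.01 ± 0.22. The integrated stress response list had 8 of 16 higher and 5 lower (0.19), with DDIT3 at 1.25 ± 0.14. Heat shock genes had 6 of 18 higher and 1 lower (5 and 1 adjusted over the list alone; 0.33), with BAG3 at 0.78 ± 0.07. Of the 9 mitochondrially encoded genes limma called 0 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; list 0.63).

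**Figure D4:**
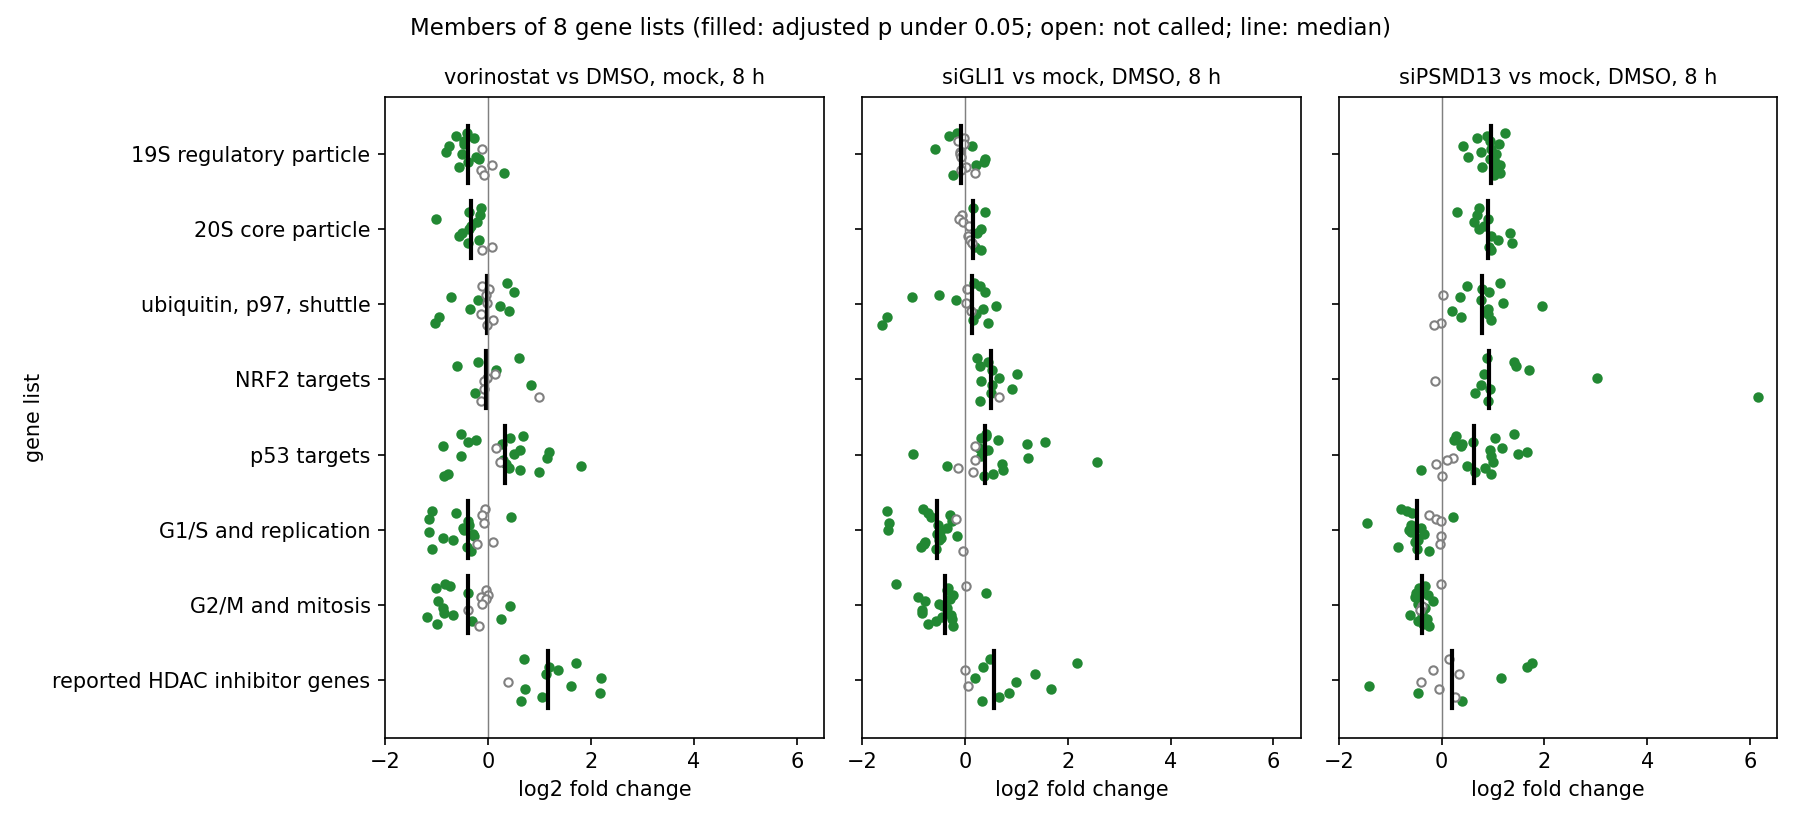
Log2 fold change of each tested member of 8 gene lists at 8 h for vorinostat in mock cells (left), siGLI1 with DMSO (middle) and siPSMD13 with DMSO (right), filled where the adjusted p was under 0.05, with the list median as a black line. The medians of the 19S and 20S lists are -0.40 and -0.33 with vorinostat and 0.96 and 0.90 with siPSMD13.

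In all, siPSMD13 changed 7580 genes at 8 h with DMSO (3589 higher, 3991 lower; 552 and 662 at least 2-fold) and 7571 at 12 h (3790 higher, 3781 lower). Of 6244 genes called at both times 6241 changed in the same direction. With vorinostat present the counts were 6526 at 8 h (3031 higher, 3495 lower) and 7348 at 12 h (3576 higher, 3772 lower). At 8 h with vorinostat 46.4% of the calls were higher, and 56.8% after each library was shifted to the same median. The 19S, 20S, NRF2, ubiquitin and p97, and p53 calls held with an estimated correlation, and the other 4 did not. The interferon call also ended with the stricter filter (0.12), without replicate 2 (0.054) and with voom weights (0.058; 0.022 to 0.12 over all other settings). The Hedgehog list was called in 4 other settings, among them without replicate 1 (0.044; 0.037 to 0.37 over all). At 12 h with DMSO it was called, with 6 of 9 genes lower (camera adjusted p = 0.017, adjusted p = 0.034 with an estimated correlation). The integrated stress response list (10 of 16 higher and 3 lower, 0.027, adjusted p = 0.36 with an estimated correlation) and the cholesterol list (10 of 17 lower and 1 higher, 0.039, adjusted p = 0.49 with an estimated correlation) were also called at 12 h and not at 8 h, and the interferon list was not called at 12 h (0.083). The other 8 lists called at 8 h were called at 12 h too (up to 0.0049), and besides the 5 above the WNT call held there with an estimated correlation (0.042).

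The knockdowns were compared with each other at 8 h. Both lie against the same mock libraries, so their fold changes correlate by chance. The observed r across genes was 0.272 with DMSO. Unchanged groups simulated against these controls gave a mean r of 0.502 (0.463 to 0.537 over 100 simulations). The simulated groups had no effects of their own, so the observed r cannot be weighed against the simulated r. The covariance was 0.111 against a simulated 0.0205, a difference of 0.0902. Of the called genes 1579 were higher in both (997 for independent lists), 1743 lower in both (1203) and 1594 moved in opposite directions. With vorinostat, r was 0.236 (simulated 0.499), the covariance 0.0662 (simulated 0.0203), and 1324 genes were higher in both, 1405 lower in both and 1296 opposite, with 782 and 958 for independent lists. The 2729 genes called in both in the same direction with vorinostat were 1560 without replicate 2. The 3 control libraries cannot be split with at least 2 on each side, so part of the excess may come from the shared controls. Between siGLI1 at 4 h and siPSMD13 at 12 h, which share no library, r was 0.226 with DMSO and 0.147 with vorinostat. In this pair with DMSO 1721 genes were higher in both (1109 for independent lists), 1597 lower in both (1093) and 1607 opposite. Genes are not independent replicates.

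Set directly against each other with DMSO, siGLI1 and siPSMD13 cells differed in 9112 genes (4490 higher and 4622 lower with siGLI1). All 17 19S genes were lower with siGLI1 (median -0.95, camera adjusted p = 1.1e-12, adjusted p = 0.13 with an estimated correlation), with PSMD3 at -1.54 ± 0.07, and 12 of 13 20S genes (median -0.74, 4.2e-07, adjusted p = 0.30 with an estimated correlation), with PSMA4 at 0.09 ± 0.06 the exception. In the ubiquitin and p97 list 14 of 16 were lower and 1 higher (8.1e-08, adjusted p = 3.4e-05 with an estimated correlation), DDI2 by -1.47 ± 0.09. NRF2 targets were lower in 8 of 12 and higher in 1 (0.0046, adjusted p = 0.30 with an estimated correlation). Ribosomal protein genes were higher in 15 of 22 (0.014, adjusted p = 0.77 with an estimated correlation), RPL11 by 0.70 ± 0.07. Mitochondrially encoded genes were higher in 8 of 9 (0.076; 0.033 with the replicate number as a block, 0.035 without replicate 1, 0.0055 without replicate 3 and up to 0.16 over all other settings), MT-CO1 by 0.96 ± 0.22. Pro-apoptotic BCL2 family genes were higher in 9 of 13 and lower in 2 (0.0498, adjusted p = 0.30 with an estimated correlation), a call that ended with the stricter filter (0.11), quantile normalization (0.054), no intensity trend (0.05), voom weights (0.062) and without replicate 2 (0.07; 0.023 to 0.11 over all other settings). Among well expressed genes, CITED2 (2.97 ± 0.10), MYO1D (2.70 ± 0.13), CDKN2B (2.66 ± 0.13) and TULP3 (2.64 ± 0.09) were higher with siGLI1, beside PSMD13 itself (6.10 ± 0.10). Among the same genes HMGA2 was 14.6-fold lower (-3.86 ± 0.14, adjusted p = 1.1e-25), followed by FAM219A (-3.26 ± 0.11), NT5E (-3.12 ± 0.14), SLC7A11 (-2.51 ± 0.15) and GDF15 (-2.50 ± 0.15). With vorinostat 8457 genes differed (4215 higher, 4242 lower).

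The response to vorinostat kept its direction in most genes after siGLI1 and was smaller at the median, more so at 4 h. Across all genes the response correlated with that in mock cells, which uses no shared library, at 0.862 at 4 h and 0.889 at 8 h. Of the 1441 genes at least 2-fold higher in mock cells at 12 h, the median at 8 h was 1.56 in mock and 1.44 in siGLI1 cells, and the 946 lower genes had -1.21 and -0.97. At 4 h the medians were 1.10 in mock and 0.79 in siGLI1 cells for the higher genes and -0.69 and -0.45 for the lower. Of the higher genes 96% kept the sign in siGLI1 cells at 8 h and 86.6% at 4 h, and of the lower genes 96.3% and 88.6%. A test of the difference itself called 1785 genes at 8 h (924 with a more positive and 861 with a more negative log2 response in siGLI1 cells) and 1308 at 4 h (761 and 547). In a gene that falls with vorinostat a more positive log2 response is a weaker fall. Of 569 called at both times 564 had the same direction. DHRS2 (-1.93 ± 0.14, adjusted p = 2e-12), CDKN2B (-1.52 ± 0.19, 3.3e-07), the guidance factor SEMA3C (-1.29 ± 0.12, 3.6e-10), ENC1 (-1.20 ± 0.13) and CLU (-1.03 ± 0.15), which rose in mock cells, had the more negative response. CDKN2B and CLU had also risen with siGLI1 alone. TNS4 (1.63 ± 0.18, 3.4e-08), the stress gene DDIT4 (1.42 ± 0.23), HMGA2 (1.41 ± 0.19) and TM4SF18 (1.37 ± 0.21) had the more positive. HMGA2 and TM4SF18 fell in both arms, and less after siGLI1. At 4 h DDIT4 did not pass (0.47 ± 0.23, 0.22), and the other 8 genes named did.

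By list, the integrated stress response genes, which fell in mock cells (median -0.47), had a more positive log2 response in siGLI1 cells in 6 of 16 (median difference 0.22; 8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00067, adjusted p = 0.32 with an estimated correlation), with DDIT4 the most. Immediate early genes (median 0.17 in mock cells) had it in 4 of 15 (6 adjusted over the list alone; 0.0054, adjusted p = 0.61 with an estimated correlation), with JUNB at 1.13 ± 0.16. G1/S genes, which fell in mock cells (median -0.39), had it in 5 of 21 (median difference 0.10; 6 adjusted over the list alone; 0.0056, adjusted p = 0.61 with an estimated correlation), with CCNE2 at 0.75 ± 0.15, and G2/M genes, which fell as well (-0.40), in 4 of 20 (median difference 0.14; 5 higher and 1 lower adjusted over the list alone; 0.012, adjusted p = 0.61 with an estimated correlation), with CCNB1 at 0.45 ± 0.08. In members that fell in both arms this is a weaker fall. p53 targets (median 0.33 in mock cells) had a more negative response in 7 of 22 and a more positive in 1 (8 and 2 adjusted over the list alone; 0.012, adjusted p = 0.61 with an estimated correlation), with TP53INP1 at -0.98 ± 0.17. At 4 h the integrated stress response list was not called and leaned the other way (1 higher and 2 lower, median -0.03, 0.76), while the G1/S (0.0013), G2/M (0.0013), p53 (0.0084) and immediate early (0.023) lists were called in the same direction, as was the WNT list upward (0.034), none of these with an estimated correlation (adjusted p = 0.82 for each). The calls of the G1/S and G2/M lists at 8 h ended with quantile normalization (0.053 each; 0.0022 to 0.053 and 0.0025 to 0.084 over all other settings), and that of the G2/M list without replicate 2 (0.084). The count of genes at 8 h was 485 without replicate 2, 782 without replicate 1 and 1128 without replicate 3, and at 4 h it was 351, 743 and 704.

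After siPSMD13 the genes that this knockdown had raised had a more negative log2 response to vorinostat. Of the 472 genes at least 2-fold higher with siPSMD13 at 12 h, 409 had a more negative response at 8 h than in mock cells, with medians of -0.11 and 0.42. The 652 genes at least 2-fold lower with siPSMD13 at 12 h had medians of 0.59 and 0.23, with 135 called for a more positive and 10 for a more negative response. The 19S genes fell in mock cells (median -0.40) and fell further here: the difference was negative in 15 of 17 at 8 h (16 adjusted over the list alone; median -0.50, camera adjusted p = 1.7e-19, adjusted p = 0.017 with an estimated correlation), with PSMD11 the lowest at -0.82 ± 0.10. In the ubiquitin and p97 list it was 9 of 16 (10 adjusted over the list alone; median -0.35, 2.1e-08, adjusted p = 1.8e-05 with an estimated correlation), with NPLOC4 at -0.84 ± 0.09, and among NRF2 targets 7 of 12 (8 adjusted over the list alone; median -0.36, 4.4e-08, adjusted p = 0.0088 with an estimated correlation), with OSGIN1 at -1.33 ± 0.17. The 20S core, which fell in mock cells too (-0.33), had 6 of 13 lower (8 adjusted over the list alone; median -0.25, 3e-04, adjusted p = 0.38 with an estimated correlation), with PSMA5 at -0.46 ± 0.10. p53 targets had 8 of 22 lower and 1 higher (10 and 1 adjusted over the list alone; 0.00043, adjusted p = 0.22 with an estimated correlation), with GDF15 at -0.71 ± 0.22, and the HDAC inhibitor list 4 of 12 lower (0.01, adjusted p = 0.27 with an estimated correlation), with CLU at -0.80 ± 0.15. Cholesterol genes had 5 of 17 higher and 1 lower (9 and 1 adjusted over the list alone; 0.00049, adjusted p = 0.28 with an estimated correlation), with INSIG1 at 0.75 ± 0.15. The ribosomal protein list was called upward (median 0.16, 0.0019, adjusted p = 0.69 with an estimated correlation) with 0 of its 22 members called by limma (0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05). At 12 h these 8 lists were called in the same direction (1.1e-17 to 0.009), and the 19S, ubiquitin and p97, NRF2 and cholesterol calls held with an estimated correlation (adjusted p = 0.0012 to 0.031). Called at 12 h alone were the heat shock list upward (0.009), the G2/M list downward (0.009) and the colon list upward (0.039), none of them with an estimated correlation (0.19 to 0.49).

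Over all genes the response in siPSMD13 cells at 8 h correlated at 0.903 with that in mock cells. Of 1415 genes at least 2-fold higher in mock cells at 4 h, the median at 8 h was 1.45 in both arms, and the 740 lower genes had -1.20 in mock and -1.26 in siPSMD13 cells. At 12 h the medians were 1.07 in mock and 1.14 in siPSMD13 cells for the higher genes and -0.79 and -1.01 for the lower. The test of the difference called 1817 genes at 8 h (666 more positive, 1151 more negative) and 2228 at 12 h (834 and 1394), and 1143 genes called at both times all had the same direction. ABHD4 (-1.72 ± 0.14, adjusted p = 4.4e-12), LIPH (-1.50 ± 0.18), the microtubule gene MAP1B (-1.48 ± 0.21), NXPE3 (-1.45 ± 0.10, 4.1e-13) and NDRG1 (-1.45 ± 0.22), which rose in mock cells, had the more negative response. HES6 (1.16 ± 0.14), MARCKSL1 (1.13 ± 0.11, 2.9e-10), the cyclin gene CCNG2 (1.08 ± 0.16), VSNL1 (1.06 ± 0.12) and the lysophosphatidic acid receptor LPAR3 (0.97 ± 0.13) had the more positive. Without replicate 2 the calls of PSMA5 (adjusted p = 0.051), CLU (0.05) and GDF15 (0.17, also without replicate 1, and 0.06 with no intensity trend) ended, with 0.00071 to 0.051, 7.4e-07 to 0.05 and 6e-05 to 0.17 over all other settings. The list call of the HDAC inhibitor genes ended without replicate 2 (0.13; 0.00056 to 0.13 over all other settings) and that of the ribosomal proteins with quantile normalization (0.2; 0.0003 to 0.2). The count of genes at 8 h was 704 without replicate 2, 955 without replicate 1 and 1271 without replicate 3, and at 12 h it was 744 without replicate 2 and 1167 without replicate 1.

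**Figure D5:**
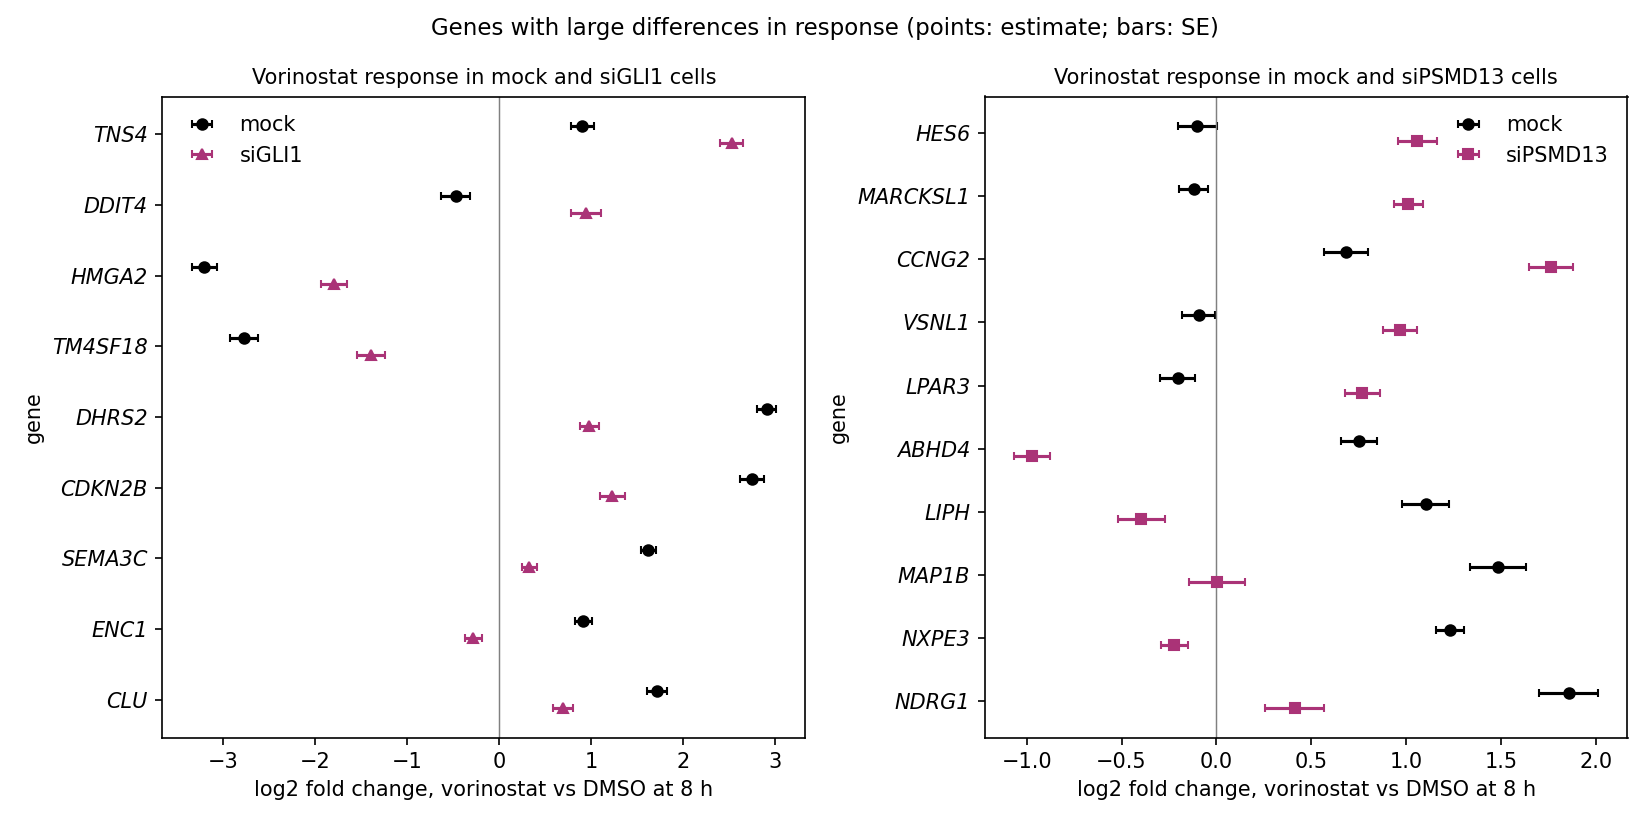
Log2 fold change of vorinostat against DMSO at 8 h in mock cells (black) and in siGLI1 (left) or siPSMD13 cells (right), with SE as bars, for 9 genes (left) and 10 genes (right) among the well expressed genes with the largest differences. DHRS2 differs by -1.93 between siGLI1 and mock cells and ABHD4 by -1.72 between siPSMD13 and mock cells.

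Within mock cells the response to vorinostat also changed with time. Between 4 and 8 h the difference was called in 3134 genes (1515 more positive, 1619 more negative at 8 h), and between 8 and 12 h in 2180 (950 and 1230). DHRS2 grew at each step, by 1.94 between 4 and 8 h and by 0.96 between 8 and 12 h. AQP3 grew by 1.26 between 4 and 8 h. CCN2 peaked at 8 h, with a difference of 0.80 from 4 to 8 h and of -0.76 from 8 to 12 h, and HMGA2 was lowest at 8 h (-0.78, then 0.79). PHLDB2 did the same (-1.16, then 0.44). TM4SF18 (-1.19) and LTBR (-0.91) fell further between 4 and 8 h, and DAAM1 was less raised at 12 than at 8 h (-0.69). From 8 to 12 h 43.6% of the calls were positive, and 56.8% after each library was shifted to the same median. Without replicate 2 the counts were 1245 (4 to 8 h) and 431 (8 to 12 h), and the latter was 1240 without replicate 1 and 1324 without replicate 3.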

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

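The test of an effect of siGLI1 at both times for 7SK and the splits balanced over experiments were chosen after the results were seen, and the other tests before theirs. The counts, genes and lists given first are differences between 2 responses to vorinostat, each shown by a test of the difference itself, and comparisons of 2 groups follow.

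The response differed between siGLI1 and mock cells in 1308 genes at 4 h and 1785 at 8 h, and between siPSMD13 and mock cells in 1817 at 8 h and 2228 at 12 h. Within mock cells it differed in 3134 genes between 4 and 8 h and in 2180 between 8 and 12 h. For each of these 6 counts 100 splits of the 12 libraries were drawn, the real one included, and 1 called as many genes, the real one. The highest of the other splits gave 314, 473, 566, 716, 1512 and 691 genes in the order above. These draws ignore that the libraries come from 3 experiments, and only 17 to 26 of each 100 set 2 libraries of each experiment against 2, as the real split does (highest others 108, 196, 394, 153, 1102 and 445). Of the 108 splits of that kind 100 were therefore drawn for each count, the real one included. Again 1 called as many genes, the real one. This is the smallest share that 100 splits can give, so chance is unlikely but not excluded. The tested difference stays in the data of the other splits, where it widens the spread within groups. Their counts therefore do not show how many genes would be called without a difference. The highest others gave 215, 259, 456, 417, 974 and 595 genes, each in a split with 10 of the 12 libraries on their real side. The way of counting distinct splits was settled after a first draw had been seen, since that draw held regroupings of the real contrast.

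The difference in log2 response between siGLI1 and mock cells at 8 h was positive for TNS4 (1.63), DDIT4 (1.42), HMGA2 (1.41), TM4SF18 (1.37), PHLDB2 (1.18), AQP3 (0.82) and ADGRF1 (0.63), and negative for DHRS2 (-1.93), CDKN2B (-1.52), SEMA3C (-1.29), ENC1 (-1.20), CLU (-1.03) and DAAM1 (-0.60). HMGA2, TM4SF18, PHLDB2 and ADGRF1 fell with vorinostat in both arms, so that their positive difference is a weaker fall. For siPSMD13 the difference was positive for HES6 (1.16), MARCKSL1 (1.13), CCNG2 (1.08), VSNL1 (1.06) and LPAR3 (0.97), and negative for ABHD4 (-1.72), LIPH (-1.50), MAP1B (-1.48), NXPE3 (-1.45), NDRG1 (-1.45), CDKN2B (-1.05) and AQP3 (-0.45). Within mock cells from 4 to 8 h the response moved in DHRS2 (1.94), AQP3 (1.26), CCN2 (0.80), HMGA2 (-0.78), LTBR (-0.91), PHLDB2 (-1.16) and TM4SF18 (-1.19), and from 8 to 12 h in DHRS2 (0.96), HMGA2 (0.79), PHLDB2 (0.44), DAAM1 (-0.69) and CCN2 (-0.76).

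By list, the camera adjusted p of these differences for siGLI1 was 0.00067 for the integrated stress response, 0.0054 for immediate early genes (JUNB 1.13), 0.0056 for G1/S (CCNE2 0.75), 0.012 for G2/M (CCNB1 0.45) and 0.012 for p53 targets (TP53INP1 -0.98). None of these 5 calls held with an estimated correlation (adjusted p = 0.32 to 0.61). At 4 h the integrated stress response list was not called (0.76), and the other 4 were (0.0013 to 0.023). For siPSMD13 it was 1.7e-19 for 19S (PSMD11 -0.82), 2.1e-08 for ubiquitin and p97 (NPLOC4 -0.84), 4.4e-08 for NRF2 (OSGIN1 -1.33), 3e-04 for 20S (PSMA5 -0.46), 0.00043 for p53 targets (GDF15 -0.71), 0.00049 for cholesterol (INSIG1 0.75), 0.0019 for ribosomal proteins and 0.01 for the HDAC inhibitor list (CLU -0.80). With an estimated correlation the 19S, ubiquitin and p97, and NRF2 calls held (adjusted p = 0.017, 1.8e-05 and 0.0088), and the other 5 did not (0.22 to 0.69).

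Genes raised by siPSMD13 alone had a more negative log2 response to vorinostat in siPSMD13 cells. For the 19S list, whose median in mock cells was already -0.40, this is a deeper fall (median difference -0.50). Shared libraries do not account for this: between the siPSMD13 effect at 12 h and the difference at 8 h, which share none, r was -0.444 (-0.462 to -0.420). The intervals of r here and below come from resampling genes, which are not independent. They leave out the error between libraries and experiments. A narrower range of values in some libraries is argued against as well, since r was -0.330 after quantile normalization. A scale compressed by a few genes cannot be told apart, because the planned shift of each library to 1 median leaves r at -0.444 by construction. The 652 genes lowered by siPSMD13 at 12 h moved the other way, with a median response of 0.59 against 0.23 in mock cells (135 called higher, 10 lower), which a ceiling on raised genes alone would not give. No other biological explanation was tested.

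With siGLI1 many genes changed although GLI1 was near the detection limit. Matches of short siRNA stretches to 3' UTRs may account for part of this: the lowest z over 7-base words was -15.4, against -4.8 for vorinostat, and the same word was lowest at 4 h (-17.3). Words below the lowest of the shuffles also occur without an siRNA: vorinostat in mock cells had 13 at 4 h, the lowest at -5.4 against -4.7 in the shuffles, and none at 8 h. Genes with any of the 3 leading words made up 44.3% of those at least 2-fold lower and 26.8% of matched genes not called, while 60.8% of genes without any word were called too, so most calls stay open. The words were chosen at 4 h for going with lower genes, in other libraries of the same knockdown. That choice favours an excess at 8 h, so the 44.3% is not independent support. A response to any siRNA cannot be told apart from the rest (r = 0.226 with siPSMD13, interval 0.204 to 0.248, between the planned bounds of 0.2 and 0.5), with no non-targeting siRNA in the design. With vorinostat, for which no bound was planned, the same r was 0.147 (0.130 to 0.164), lower than with DMSO and under 0.2. On the third principal component, with 11.9% of the variance, both arms lie on the same side of mock. Mock lies between the arms on the second component. A further axis uncorrelated with that one would place both arms so even without a shared response, so this cannot decide. Loss of Hedgehog output stays open (camera adjusted p = 0.52). The list's mean lay -0.65 from that of other genes, with an interval of -1.46 to 0.16. This holds both no difference and a fall of over 2-fold against other genes, so the bound planned against it was too weak.

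7SK (4.32 ± 0.71, adjusted p = 1.4e-06), RN7SL4P (4.74 ± 0.98, 6.4e-05) and RN7SL5P (4.16 ± 1.02, 0.00057), RNAs without a poly(A) tail, were higher with siGLI1 and DMSO at 8 h, and were picked after their values were seen. An effect of siGLI1 present at both times is argued against, since the median log2 fold change was -0.99 at 4 h, -0.23 times that at 8 h, with 7SK at -0.99 ± 0.71 (65 reads against 185 in mock cells), RN7SL4P at -1.94 ± 0.98 and RN7SL5P at -0.98 ± 1.02. Carry-over of RNA without a tail may be the source: within groups, 7SK and the RN7SL mean correlated over the 42 libraries at r = 0.838 (rho 0.847, permutation p = 1e-05 for each, the smallest that 100000 permutations can give), and at 0.853 without the 2 farthest libraries. Their median log2 fold change at 8 h was also above 0 with siPSMD13 (2.06) and with vorinostat (1.42), which is given without a test. Whether the cells held more of these RNAs was not tested.

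For the 17 other comparisons the 6 libraries allow 10 splits, too few for a share under 0.05. In each, 1 split, the real one, called as many genes. The effect itself widens the spread within groups in the other splits, so their counts are not those without an effect. Real counts and the highest of the other splits were 8740 and 0, 9965 and 0, and 9600 and 1 for vorinostat in mock cells at 4, 8 and 12 h, 7688 and 8, and 9543 and 0 in siGLI1 cells at 4 and 8 h, and 10117 and 0, and 10099 and 5 in siPSMD13 cells at 8 and 12 h. For siGLI1 they were 8496 and 23, and 8458 and 7 with DMSO, and 8217 and 2, and 7770 and 3 with vorinostat (4 and 8 h). For siPSMD13 they were 7580 and 1, and 7571 and 1 with DMSO, and 6526 and 4, and 7348 and 35 with vorinostat (8 and 12 h). For siGLI1 against siPSMD13 they were 9112 and 2 with DMSO and 8457 and 2 with vorinostat. Among the 4 splits of each comparison that part as many of the 3 pairs, the highest other was 3.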

How the results depend on the processing

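The fit with voom weights was chosen after seeing the data, and all other settings before. All 23 counts of called genes stayed within 1.5 times in the 8 settings that keep every replicate. With fewer libraries the counts for differences of the vorinostat response fell. Leaving out 1 replicate number at a time gave 431 to 1324 genes (mock, 8 to 12 h), 1245 to 2401 (mock, 4 to 8 h), 351 to 743 (siGLI1, 4 h), 485 to 1128 (siGLI1, 8 h), 704 to 1271 (siPSMD13, 8 h) and 744 to 1674 (siPSMD13, 12 h). The lowest was without replicate 2 each time, and of its genes 427, 1225, 346, 479, 693 and 736, in the same order, were also called with all libraries. The correlation of the siGLI1 and siPSMD13 effects ranged over all settings from 0.255 to 0.298 with DMSO and from 0.226 to 0.259 with vorinostat (at least 0.267 and 0.228 with 1 replicate number left out). The genes called in both in the same direction ranged from 2334 to 3571 and from 1560 to 3050 (with vorinostat at most 2379 with 1 replicate number left out). With an estimated correlation the lists called were 0 for vorinostat, 0 for siGLI1, 5 for siPSMD13, 0 and 3 for the siGLI1 and siPSMD13 differences, and 1 for siGLI1 against siPSMD13. Quantile normalization left 6 of the 11 lists for vorinostat and 3 of the 5 for the siGLI1 difference, and the stricter filter called 7 for vorinostat, 6 of the 11 and the interferon list. Under quantile normalization CDC20 with vorinostat went from -0.00 to 0.20. The 59 entries of gene and comparison chosen by size of change kept their calls in all 649 pairs of entry and setting. Some genes stand in several entries, and a choice of large changes favours calls that hold. The leading word kept a z between -15.5 and -14.9. The replicate block changed the calls of 2 lists, named with their comparisons, and called 30 more of 684 pairs of listed gene and comparison. GLI1 has no value under the stricter filter, and the change of pseudocount did not apply. Why quantile normalization or the filter moved lists was not tested.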

Other observations

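The 3' UTR tests of target sites and of the base composition of GTGTGTA were run after the leading words had been seen, with their bounds written first, and the tests of the base composition of GCAATGC and TCCACTC were chosen after their values were seen. BCL2 family genes moved on both sides with vorinostat in mock cells at 8 h. Of 13 pro-apoptotic members 6 rose and 5 fell (camera adjusted p = 0.53, the test leaning up at a median of -0.00), with BMF at 3.41 ± 0.19, BCL2L11, the gene of BIM, at 1.26 ± 0.10 and BNIP3L at 1.19 ± 0.10. Of 4 pro-survival members 1 rose and 2 fell (0.48), with BCL2L1, the gene of BCL-xL, at -1.23 ± 0.09 and MCL1 at 0.23 ± 0.06. BCL2L1 fell with siGLI1 as well (-0.93 ± 0.09; list 2 of 4 lower, 0.32), and BCL2 with siPSMD13 (-1.34 ± 0.19; list 2 higher and 1 lower, 0.80). With siPSMD13 the pro-apoptotic list had 5 higher and 4 lower (0.70, the test leaning up at a median of -0.10), with PMAIP1 at 1.03 ± 0.08 and BAK1 at 0.96 ± 0.08.

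Among HDAC and sirtuin genes 10 of 18 rose and 3 fell with vorinostat (0.069; 0.045 without replicate 1 and 0.045 to 0.14 over all other settings), with SIRT4 at 2.63 ± 0.24, HDAC5 at 1.28 ± 0.08 and HDAC7 at -1.54 ± 0.11, and HDAC2 at -0.07 ± 0.05 not called (-0.12, adjusted p = 0.045, after a shift to the same median, and 0.045 to 0.48 over all other settings). With siGLI1 the list had 5 higher and 5 lower (0.83), with HDAC4 at -1.60 ± 0.15. Interferon-responsive genes rose in 6 of 13 and fell in 3 with vorinostat (0.072; 0.038 to 0.16 over all other settings, called with the stricter filter), with OASL at 3.19 ± 0.19 and IFIT1 at 2.63 ± 0.23. With siGLI1 6 of 13 rose and 2 fell (0.42), with IFI6 at 1.20 ± 0.17 and OAS3 at -1.24 ± 0.11. Immediate early genes rose in 6 and fell in 4 of 15 with vorinostat (0.53), with FOS at 1.75 ± 0.21 and FOSL1 at -1.90 ± 0.10. With siGLI1 3 rose and 8 fell (0.16), with JUN at 1.53 ± 0.13 and EGR1 at -2.14 ± 0.21. CDH1 fell with siGLI1 (-0.60 ± 0.06), with 3 of 7 genes of the colon list lower (2 adjusted over the list alone, 0.12). ZEB1, the repressor of CDH1, rose (1.83 ± 0.19), as it did with siPSMD13 (1.39 ± 0.19). With vorinostat in mock cells both genes rose, as given above, so they did not always move in opposite directions. CYP51A1 of cholesterol synthesis fell with siGLI1 (-1.62 ± 0.12; list 5 of 17 higher, 6 lower, 0.74), and with siPSMD13 the list had 2 higher and 9 lower (3 and 10 adjusted over the list alone, 0.078; 0.032 with quantile normalization and 0.032 to 0.12 over all other settings), and was called at 12 h (0.039, adjusted p = 0.49 with an estimated correlation).

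The leading 3' UTR words of genes lower with siGLI1 may be target sites shared with the GLI1 siRNAs, whose sequences were not used here. The GLI1 transcript holds all 3 words in sense. Of 2941 transcripts of like length 3.4% hold all 3 or their reverse complements, and 0.75% hold all 3 in sense. For GTGTGTA a base composition that goes with low expression is argued against, since the word in coding sequence had a z of -1.5 (-15.4 in 3' UTRs). For TCCACTC such a composition may have a part, since its z in coding sequence was -4.1 (-7.4 in 3' UTRs), which sites in coding sequence could also give. For GCAATGC, at -3.1 and -9.8, this cannot be told apart, since the ratio lies between the bounds. With siPSMD13 the z of GTGTGTA was -1.2 and with vorinostat 1.8. The lowest word for siPSMD13, TCCAGTA (-7.4), stands in the PSMD13 transcript. How many transcripts of like length hold it was not counted, so this cannot be weighed.

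Effects of siRNA and vorinostat were compared between libraries that share none. siGLI1 at 4 h and vorinostat at 8 h correlated at r = 0.148 (0.127 to 0.170), between the planned bounds, so a shared response cannot be told apart from none. Without 541 cell cycle and co-varying genes r was 0.146. These are a small part of the 14603 genes, and the co-varying ones were picked by residuals within groups. The test therefore cannot decide whether a slower cell cycle has a part. For siPSMD13 at 12 h r was 0.086 (0.066 to 0.108), whose interval crosses the planned bound of 0.1. As with siPSMD13, genes raised by siGLI1 at 4 h had a more negative log2 response to vorinostat at 8 h, with r = -0.264 (-0.292 to -0.235) and no shared library, so shared libraries do not account for it. Of 476 such genes 347 (72.9%) had a more negative response than in mock cells. The 1041 genes lowered by siGLI1 at 4 h had a median response of 0.27 against 0.10 in mock cells, with 146 called higher and 27 lower.

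Mitochondrial rRNA and tRNA genes (9) took a larger mean share of reads with either siRNA and with vorinostat in the groups given here. No test was run on these shares. With DMSO at 8 h they held 0.571% ± 0.09 of reads in siGLI1 libraries and 0.462% ± 0.0446 in siPSMD13 libraries, against 0.277% ± 0.0418 in mock cells (SD, n = 3). With vorinostat they held 0.43% ± 0.0483 in mock, 0.797% ± 0.0758 in siGLI1 and 0.797% ± 0.0511 in siPSMD13 cells. At 4 h with DMSO the share was 0.435% ± 0.0209 with siGLI1 and 0.293% ± 0.0259 in mock cells.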
